A study of Mus musculus with 8 samples.

How the data were processed

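Total RNA of T29 cells transduced with MigR1 or MigR1-Ik1ER and treated with 4OHT or ethanol was labelled with biotin from 2.0 to 2.5 µg and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds 1 column per array with log2 expression values, which the range of the values bears out, and the values were made with RMA per the submitters' processing notes. The version of RMA, the probe set definition file and the genome build are not given in the sources used here. RMA sets arrays processed together to a common distribution and summarises each probe set on a log2 scale, so that a global shift of RNA content cannot be seen and the changes of dim genes are compressed. Whether all 8 arrays were processed together is not given in the sources used here, and the array medians ranged from 5.36 to 5.43. No detection calls were used. As a gauge of background, the 27 Bacillus control probe sets had a median of 3.33 and a highest mean of 5.27.

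Gene names came from the platform annotation. Of the probe sets, 64 are controls, 34945 have 1 gene symbol, 932 have several and 9160 are not listed with a symbol, and 34741 of those with 1 symbol were matched by gene identifier to a RefSeq gene table, which changed 0 symbols. Probe sets with 1 symbol entered the tests, with the probe set of highest mean over the 8 arrays standing for its gene and those ending in _x_at used only where a gene had no other, which gave 18193 genes. No named gene had another probe set called in the opposite direction for 4OHT in Ik1ER cells. Of the 88 named genes called there, 33 had another probe set above the highest Bacillus control mean, and for 19 of these at least 1 was not called. The 19 were Myl4, Maf, Igfbp7, Dntt, Ikzf3, Btg1, Bcl2l2, Ddx21, Greb1, Tnfaip3, Trp53inp1, Sesn1, Trib3, Cd4, Themis, Jun, Nfkbia, Gbp7 and Pdlim5. Calls of other probe sets used p-values adjusted over 45037 probe sets, which is stricter than over 18193 genes. On that scale the probe sets that stood for Themis, Trib3 and Ddx21 were not called either. A probe set that was not called thus need not differ in size from the one used. No filter on dim genes was applied in the main analysis.

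Group means were fitted to all 8 arrays with lmFit and moderated with eBayes of limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom. The 5 contrasts were 4OHT against ethanol in Ik1ER cells, the same in MigR1 cells, the difference between these effects, and Ik1ER against MigR1 cells in ethanol and in 4OHT. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, and genes with an adjusted p under 0.05 were called. Errors beside group means are SD over 2 arrays and errors beside fold changes are standard errors from limma, with the spread pooled over the groups. The Ikzf1 and Esr1 probe sets were compared between lines by exact permutation tests of 4 against 4 arrays, among 16 probe sets examined in this way, without adjustment.

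The 28 gene lists covered the Notch pathway, the T cell receptor complex, early thymocyte genes, T lineage transcription factors, thymocyte maturation and homing, the Ikaros family, the NuRD complex, Polycomb repressive complex 2, and stem and progenitor genes. They also covered S phase, G2 and mitosis, cell cycle inhibitors, the BCL2 family, glycolysis, MYC-driven ribosome biogenesis, sterol biosynthesis and estrogen receptor targets. The rest were the interferon response, cytokine and STAT5 response, immediate early genes, p53 targets, the integrated stress response, TGF-beta signalling, and markers of B cells, myeloid cells, cytotoxic lymphocytes, erythroid cells and stromal cells. Of 438 members 412 were measured. Lists of at least 5 measured members were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists. With a correlation estimated for each list no call remained in any contrast. Counts adjusted over the list alone used the same p-values, adjusted within the list.

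The groups, contrasts, gene lists, naming rule and most alternatives were fixed before the data were examined. By that rule the text names the 12 largest rises and 12 largest falls in Ik1ER cells among called genes whose 2 4OHT arrays both lie on the same side of both ethanol arrays, leaving out predicted and clone-named genes. It names 5 of each for the other contrasts, or the 5 of smallest p where none was called, the 4 members of smallest p of each list, and the Ikaros family. Genes named outside the rule are said to be so. These alternatives were the replicate number as a block, a filter keeping the 10916 genes with a mean above the median of all probe sets (5.40), eBayes with trend and robust settings, and repeated quantile normalization. Others were centring of each array on its median, the mean over the probe sets of a gene, every probe set on its own, only the arrays of the groups compared, an absolute log2 fold change of at least 1, camera with an estimated correlation, and leaving out each array in turn. When an array was left out, the lone array of its group was assumed to vary like the other groups. The alternatives without both replicate 2 arrays of Ik1ER and with the 3' to 5' difference of the transferrin receptor as a covariate were added after seeing the data.

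The contrasts of 4OHT in Ik1ER cells and of the lines in 4OHT share the Ik1ER 4OHT arrays, so their overlap was set beside 50 simulations of unchanged arrays and the overlap of independent lists; with 2 arrays the shared group could not be split. The fit was tested on simulated data for 18193 genes, with 67, 67 and 66 of them changed by 0.5, 1 and 2 on the log2 scale. For 4OHT in Ik1ER cells it recovered 52.2%, 91% and 100% of these, with 7 false among 169 calls, and for the difference of effects 11.9%, 71.6% and 97%, with 6 false among 126. For 4OHT in Ik1ER cells camera found a simulated list of 16 genes shifted by 0.3 and called 0 of 100 unshifted lists. In these simulations genes varied independently of each other. The unshifted lists thus cannot show how often camera calls lists of correlated genes at its preset correlation.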

Results

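Gene expression was measured in T29 cells, a mouse thymic lymphoma line that the series text calls deficient in Ikaros. Ikaros, encoded by Ikzf1, is a zinc finger transcription factor needed for lymphocyte development and acts as a tumour suppressor in T cell precursors. The cells carried either the retroviral vector MigR1 or MigR1 with Ik1ER, an Ikaros protein whose activity is switched on by 4-hydroxytamoxifen (4OHT). Each line was treated for 24 h with 100 nM 4OHT or with its solvent, ethanol. Total RNA from the 4 groups was hybridised to 8 Affymetrix arrays, 2 per group. The number of arrays limits the precision. The labels do not say that arrays of a group came from separate cultures, so that p-values measure the spread between arrays, which may be technical. The SD of the log2 difference between the 2 arrays of a group ranged from 0.147 (MigR1, ethanol) to 0.214 (Ik1ER, 4OHT). The replicate 2 arrays of the Ik1ER line stood apart in their control probe sets. The 3' probe set of the transferrin receptor exceeded the 5' probe set by 1.66 in ethanol and 1.91 in 4OHT, against 1.15 to 1.39 on the other 6 arrays. Hybridization controls averaged 8.86 on Ik1ER 4OHT replicate 2, against 9.41 to 9.54 on all other arrays. Those of 18S rRNA averaged 10.07 on Ik1ER ethanol replicate 2, against 8.54 to 9.18 on all other arrays. Positions in the genome are not given, since the sources used here name no genome build.

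Ikzf1 itself was measured first, by 2 probe sets that differed. The dimmer one in MigR1 cells read 8.13 ± 0.02 and 8.34 ± 0.25 in MigR1 cells in ethanol and 4OHT (log2, SD, n = 2), and 10.88 ± 0.40 and 10.86 ± 0.58 in Ik1ER cells. Over both treatments it was 2.64 higher on the log2 scale, or 6.22-fold, in the 4 Ik1ER arrays than in the 4 MigR1 arrays (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 arrays allow). The other probe set, which stood for the gene in the tests across genes, lay between 10.11 and 10.30 in all 4 groups. Both thus read above the highest Bacillus control mean (5.27) in MigR1 cells, so that the transcript readings do not show the deficiency. The line difference of the latter was -0.07 (exact permutation test, p = 0.514). One of the 3 probe sets of Esr1, the estrogen receptor gene, read 1.84-fold higher in the Ik1ER line (exact permutation test, p = 0.0286), while the other 2 differed by -0.04 and 0.02. A probe set of Ikzf2 read lower in the Ik1ER line at the same p (-0.36), so that 3 of 16 probe sets examined reached it, without adjustment. Of the Ikaros relatives, Ikzf3 (Aiolos) rose with 4OHT in Ik1ER cells by 0.43 (SE 0.07, adjusted p = 0.0109). Ikzf2, Ikzf4 and Ikzf5 differed by 0.24, -0.07 and -0.08 and were not called, nor was Ikzf1 (-0.19, adjusted p = 0.529). The call of Ikzf3 was lost without Ik1ER ethanol replicate 1 or replicate 2, with an adjusted p of at most 0.0722.

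**Figure D1:**
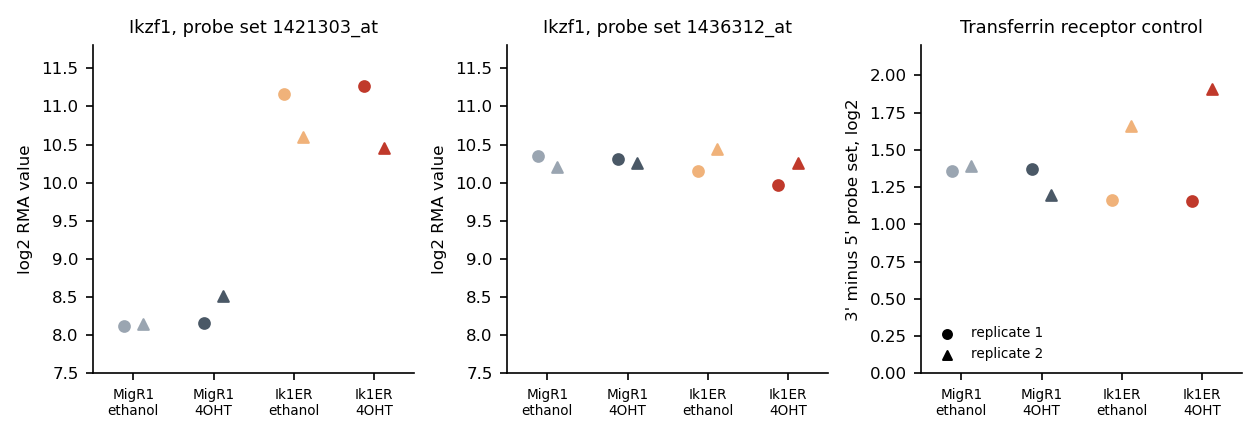
Log2 RMA values of the 2 probe sets of Ikzf1 and, on the right, the log2 difference between the 3' and 5' control probe sets of the transferrin receptor, for each array (circles replicate 1, triangles replicate 2, n = 2 per group). The leftmost probe set averages 10.88 and 10.86 in the Ik1ER groups against 8.13 and 8.34 in the MigR1 groups, and the control difference reaches 1.66 and 1.91 on the replicate 2 arrays of Ik1ER cells.

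The comparison the study was built for asks which genes change when Ikaros activity is induced, as 4OHT against ethanol in Ik1ER cells. The largest measured rises were those of Ms4a4b and Ms4a4d, which encode membrane proteins with 4 spanning segments, by 3.02 (SE 0.14, 8.09-fold, adjusted p = 8.44e-05) and 2.71 (SE 0.17, adjusted p = 0.000286) on the log2 scale. Ms4a4b went from 5.74 ± 0.31 to 8.75 ± 0.16 (SD, n = 2). The protease inhibitor gene Serpini1 (2.11), the myosin light chain gene Myl4 (2.07), the chemokine receptor gene Cxcr6 (2.03) and the potassium channel gene Kcna2 (2.02) also rose. So did the transketolase-like gene Tktl1 (1.99), the transcription factor gene Maf (1.99), Gimap7 (1.98), Mcoln3 (1.97), Igfbp7 (1.87) and Ms4a6b (1.86). A second probe set of Igfbp7, nearly as bright (mean 7.17 against 7.28), read 0.01 (adjusted p = 0.976), and the change of this gene is therefore open. The 2 probe sets of Myl4 also differed, as the other one (mean 5.51) read -2.6e-05 and was not called. Among the deepest falls, Lmcd1, which encodes a LIM domain protein, fell by 2.99 (SE 0.14, 7.96-fold, adjusted p = 8.44e-05). The ubiquitin ligase gene Rnf182 fell by 2.96 (SE 0.18, adjusted p = 0.000279) and the adhesion molecule gene Mpzl2 by 2.92 (SE 0.16, adjusted p = 0.000146). Lmcd1 went from 11.19 ± 0.29 to 8.19 ± 0.20 (SD, n = 2). They were followed by the sodium channel subunit gene Scn4b (-2.84), the interferon-activated genes Ifi204 (-2.64) and Ifi202b (-2.37), and Uaca (-2.24). Lhfp (-2.13), the small heat shock protein gene Cryab (-2.13), the iron homeostasis gene Hfe (-2.13), Ifitm2 (-2.04) and Gpr83 (-1.92) came next. Ifi204 and Ifi202b, and likewise the Ms4a genes, belong to families of related genes, so that a probe set may read more than 1 member. Sequences were not compared here. In ethanol Ms4a4d (3.28), Gimap7 (4.31), Kcna2 (4.65) and Cxcr6 (4.78) read below the highest mean of the Bacillus control probe sets (5.27). So did Ifi204 (3.40), Rnf182 (4.71), Cryab (5.05) and Lhfp (5.07) in 4OHT. The changes of these genes may be compressed, and their sizes and ranks are open.

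In all, limma called 973 of 18193 genes in this comparison, 516 higher and 457 lower, of which 78 and 75 changed by at least 1 on the log2 scale. The genes named in the previous paragraph kept their calls when each array in turn was left out. They had been picked from the same arrays for large and separated changes, which made this likely. Leaving out a MigR1 array cannot change their fold changes, only the pooled spread. The count was 439 without Ik1ER ethanol replicate 1, 440 without Ik1ER ethanol replicate 2 and 412 with the 4 Ik1ER arrays alone. It was 388 without both replicate 2 arrays of Ik1ER, an alternative chosen after seeing the data. It was 1560 with the 3' to 5' difference of the transferrin receptor as a covariate, also chosen after seeing the data.

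**Figure D2:**
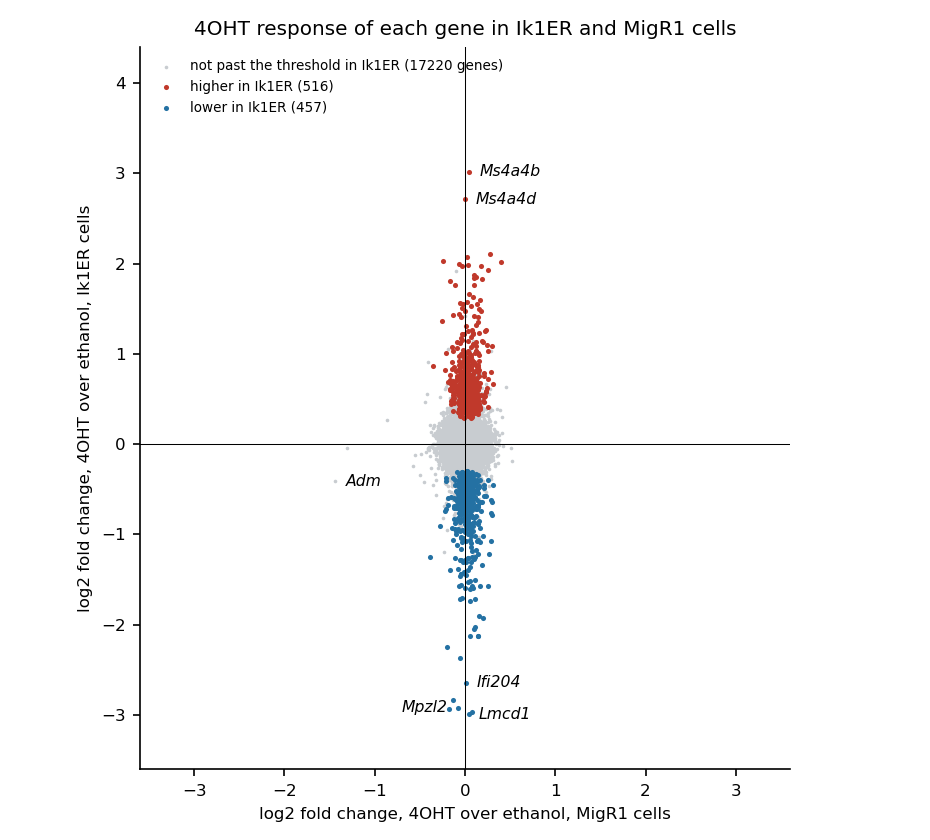
Log2 fold change of each of the 18193 genes with 4OHT over ethanol in MigR1 cells (horizontal axis) and in Ik1ER cells (vertical axis), each from 2 arrays per group. The 516 genes higher and the 457 lower in Ik1ER cells spread along the vertical axis, with medians of 0.03 and 0.02 in MigR1 cells, and Adm lies at -1.44 in MigR1 cells.

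Genes of the Notch pathway, which drives early T cell development and many T cell leukaemias, were lower. Of 20 measured members 5 fell, none rose and 15 were not called, or 8 lower adjusted over the list alone. The median of the list was -0.24 (camera, adjusted p = 0.000239, adjusted p = 0.243 with an estimated correlation). Fjx1 changed by -0.83 (SE 0.08, adjusted p = 0.00109), the Notch feedback inhibitor Nrarp by -0.74 (SE 0.10, adjusted p = 0.00679). Hes1, a repressor and direct Notch target, changed by -0.83 (SE 0.17, adjusted p = 0.0304). The changes of Ptcra, the pre-T cell receptor alpha chain, and of Myc were -0.61 (SE 0.13, adjusted p = 0.0408) and -0.48 (SE 0.08, adjusted p = 0.0124). Fjx1 and Nrarp kept their calls with each array left out. Myc lost its call without Ik1ER ethanol replicate 1 (adjusted p = 0.0823), and Hes1 without Ik1ER ethanol replicate 1 or 2 or Ik1ER 4OHT replicate 2 (at most 0.162). Ptcra lost its call without any array except Ik1ER 4OHT replicate 2 (at most 0.206).

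Members of the T cell receptor complex and its proximal signalling moved in both directions. Of 18 measured, 6 rose, 3 fell and 9 were not called, or 10 and 4 adjusted over the list alone. The coreceptor chains rose, Cd8b1 by 1.56 (SE 0.26, 2.94-fold, adjusted p = 0.0140), Cd8a by 1.84 (SE 0.32, 3.59-fold, adjusted p = 0.0160) and Cd4 by 0.72 (SE 0.14, adjusted p = 0.0255). So did the adhesion molecule gene Cd2 (0.87), the phosphatase gene Ptprc (0.41) and Themis (0.47). Of the CD3 chains, which carry the receptor's signal, those encoded by Cd3g, Cd3e and Cd3d were lower. Cd247, which encodes the zeta chain, was measured and not called. Cd3g changed by -0.69 (SE 0.09, adjusted p = 0.00522), Cd3e by -0.43 (SE 0.07, adjusted p = 0.0151) and Cd3d by -0.49 (SE 0.11, adjusted p = 0.0419). Cd8a, Cd4, Themis, Cd3e and Cd3d are named here because they complete the called members, a choice made after their values were seen. Cd8b1 read 10.20 ± 0.64 in Ik1ER cells in 4OHT and 8.65 ± 0.32 in ethanol (SD, n = 2). The list as a whole was higher (median 0.23, camera, adjusted p = 0.00969, adjusted p = 0.296 with an estimated correlation), but not with dim genes left out (adjusted p = 0.210, the highest of 12 settings, against 0.00618 for the lowest). Cd3g alone of the 9 kept its call with each array left out. Cd8a and Cd8b1 lost theirs without Ik1ER ethanol replicate 2 (adjusted p = 0.104 and 0.0909), and Cd3e without Ik1ER ethanol replicate 1 or Ik1ER 4OHT replicate 1 (at most 0.0988). Those of Cd2, Ptprc and Cd4 needed both of these and Ik1ER ethanol replicate 2 (at most 0.0908, 0.102 and 0.150). Themis was called with all arrays or without Ik1ER ethanol replicate 2, and Cd3d with all or without Ik1ER 4OHT replicate 1 (at most 0.178 and 0.207).

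Genes of thymocyte maturation, homing and egress were higher as a list. Of 16 measured members 4 rose, none fell and 12 were not called, or 7 higher and 1 lower adjusted over the list alone. The median was 0.24 (camera, adjusted p = 0.00418, adjusted p = 0.220 with an estimated correlation), and the call was lost with dim genes left out (adjusted p = 0.243, the highest of 12 settings, against 0.00138 for the lowest). The integrin gene Itgae rose by 1.01 (SE 0.15, adjusted p = 0.00949) and its partner Itgb7 by 0.47 (SE 0.08, adjusted p = 0.0170). The transcription factor genes Foxo1 and Klf2, which control homing receptors, rose by 0.91 (SE 0.15, adjusted p = 0.0124) and 0.48 (SE 0.09, adjusted p = 0.0245). Without Ik1ER ethanol replicate 2 none of the 4 was called. Foxo1, Itgb7 and Klf2 were also lost without Ik1ER ethanol replicate 1, Itgb7 and Klf2 without Ik1ER 4OHT replicate 1, and Klf2 without either MigR1 ethanol array. The highest adjusted p with any array left out was 0.0669 for Itgae, 0.0795 for Foxo1, 0.0993 for Itgb7 and 0.132 for Klf2. Of 16 early thymocyte stage genes, Cd44, which marks early progenitors and also memory T cells, rose by 1.76 (SE 0.22, adjusted p = 0.00451). It rose from a mean of 4.66, below the highest control, so that the size of this change is open. Dntt, the terminal transferase of receptor gene rearrangement, changed by -0.52 (SE 0.08, adjusted p = 0.0104, and 0.0705 without Ik1ER ethanol replicate 2). Ptcra fell as above, and 13 were not called, or 1 higher and 3 lower adjusted over the list alone.

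Cell cycle inhibitors were higher, with 4 of 15 risen, none fallen and 11 not called, or 6 higher adjusted over the list alone. The median was 0.30 (camera, adjusted p = 0.00119, adjusted p = 0.220 with an estimated correlation). Btg2 and Btg1, which restrain proliferation, rose by 0.58 (SE 0.08, adjusted p = 0.00727) and 0.55 (SE 0.09, adjusted p = 0.0124). The cyclin-dependent kinase inhibitor gene Cdkn2d rose by 0.68 (SE 0.11, adjusted p = 0.00997) and Rb1 by 0.39 (SE 0.09, adjusted p = 0.0438). Among p53 targets 4 of 14 rose, none fell and 10 were not called, or 7 higher and 1 lower adjusted over the list alone (median 0.22, camera, adjusted p = 0.00130, adjusted p = 0.220 with an estimated correlation). They were Btg2, which both lists hold, Trp53inp1 (0.87, SE 0.10, adjusted p = 0.00234), Sesn1 (0.48, SE 0.08, adjusted p = 0.0175) and Zmat3 (0.59, SE 0.14, adjusted p = 0.0468). Other probe sets of Sesn1 (means 8.83 and 8.71) read 0.16 and 0.25 and were not called. Trp53inp1 kept its call with each array left out. Btg2 lost its call without Ik1ER ethanol replicate 2 (adjusted p = 0.0540), Cdkn2d without Ik1ER ethanol replicate 1 (0.0646), and Btg1 without Ik1ER ethanol replicate 1 or Ik1ER 4OHT replicate 1 (at most 0.0749). Sesn1 lost its call without any 1 of the 4 Ik1ER arrays (at most 0.109). Rb1 lost it without any array except Ik1ER ethanol replicate 2 and Zmat3 without any except Ik1ER 4OHT replicate 1 (at most 0.203 and 0.204).

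Genes of G2 and mitosis were slightly higher in Ik1ER cells with 4OHT, with 18 of 19 above 0. limma called none of them over all genes or adjusted over the list alone, and the median was 0.15 (camera, adjusted p = 0.000721, adjusted p = 0.380 with an estimated correlation). Cenpe (0.37), Ccnb2 (0.27), Top2a (0.29) and Nusap1 (0.21) had the smallest p-values of the list. Genes of MYC-driven ribosome biogenesis were slightly lower, with 19 of 20 below 0 and a median of -0.11 (camera, adjusted p = 0.00119, adjusted p = 0.380 with an estimated correlation). Only the helicase gene Ddx21 was called among them (-0.33, SE 0.07, adjusted p = 0.0399), or 2 lower adjusted over the list alone. Ddx21 had another bright probe set (mean 10.18), which read -0.06 (limma, adjusted p = 0.903), so that its change is open. Its call was lost without any 1 of the 8 arrays (adjusted p at most 0.205). That of the list was lost without Ik1ER ethanol replicate 1 (adjusted p = 0.0609, the highest of 12 settings, against 0.000141 for the lowest). No gene of S phase and replication was called among 20.

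**Figure D3:**
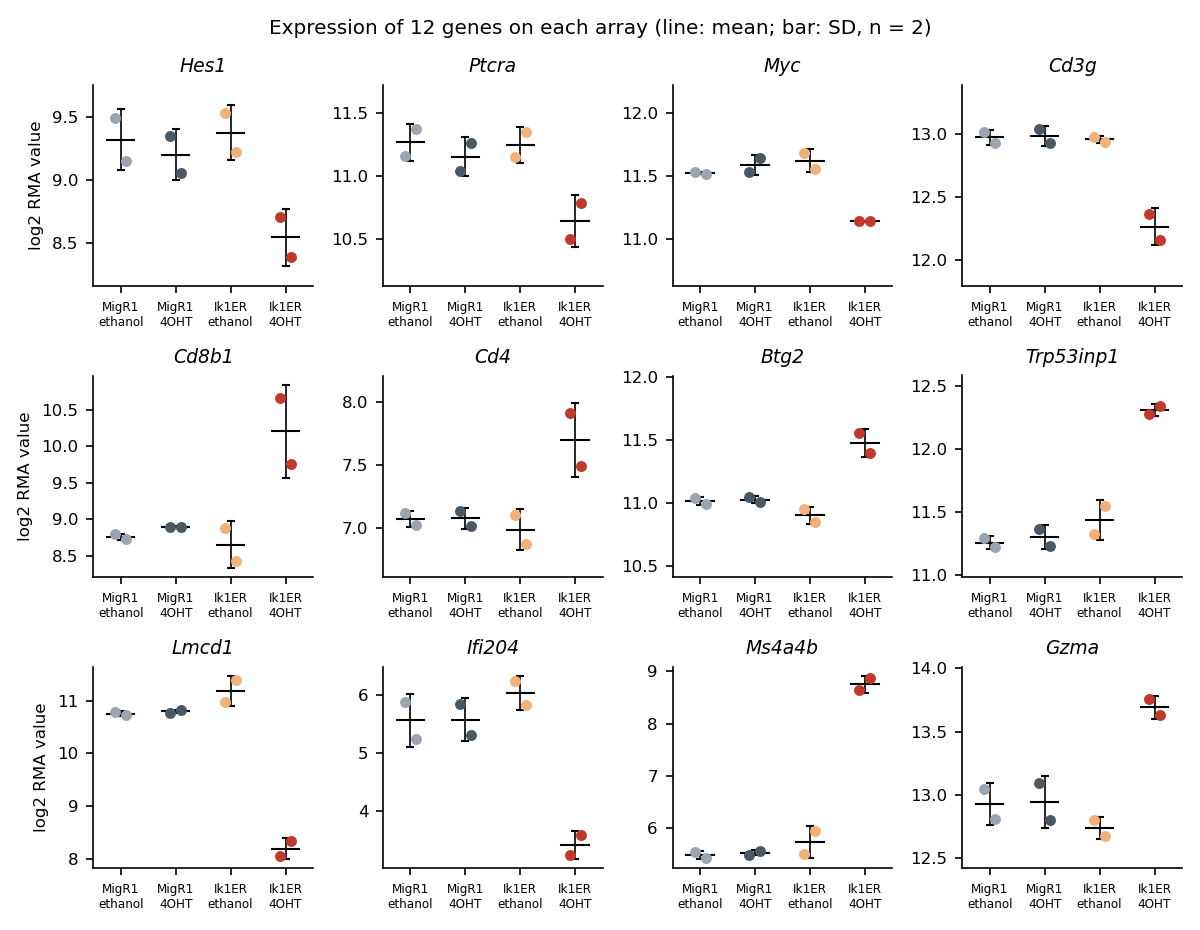
Log2 RMA values of 12 genes on each array in the 4 groups (points single arrays, lines means, bars SD, n = 2). Hes1, Ptcra, Myc, Cd3g, Lmcd1 and Ifi204 are lower and Cd8b1, Cd4, Btg2, Trp53inp1, Ms4a4b and Gzma higher in Ik1ER cells with 4OHT than in Ik1ER cells with ethanol.

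**Figure D4:**
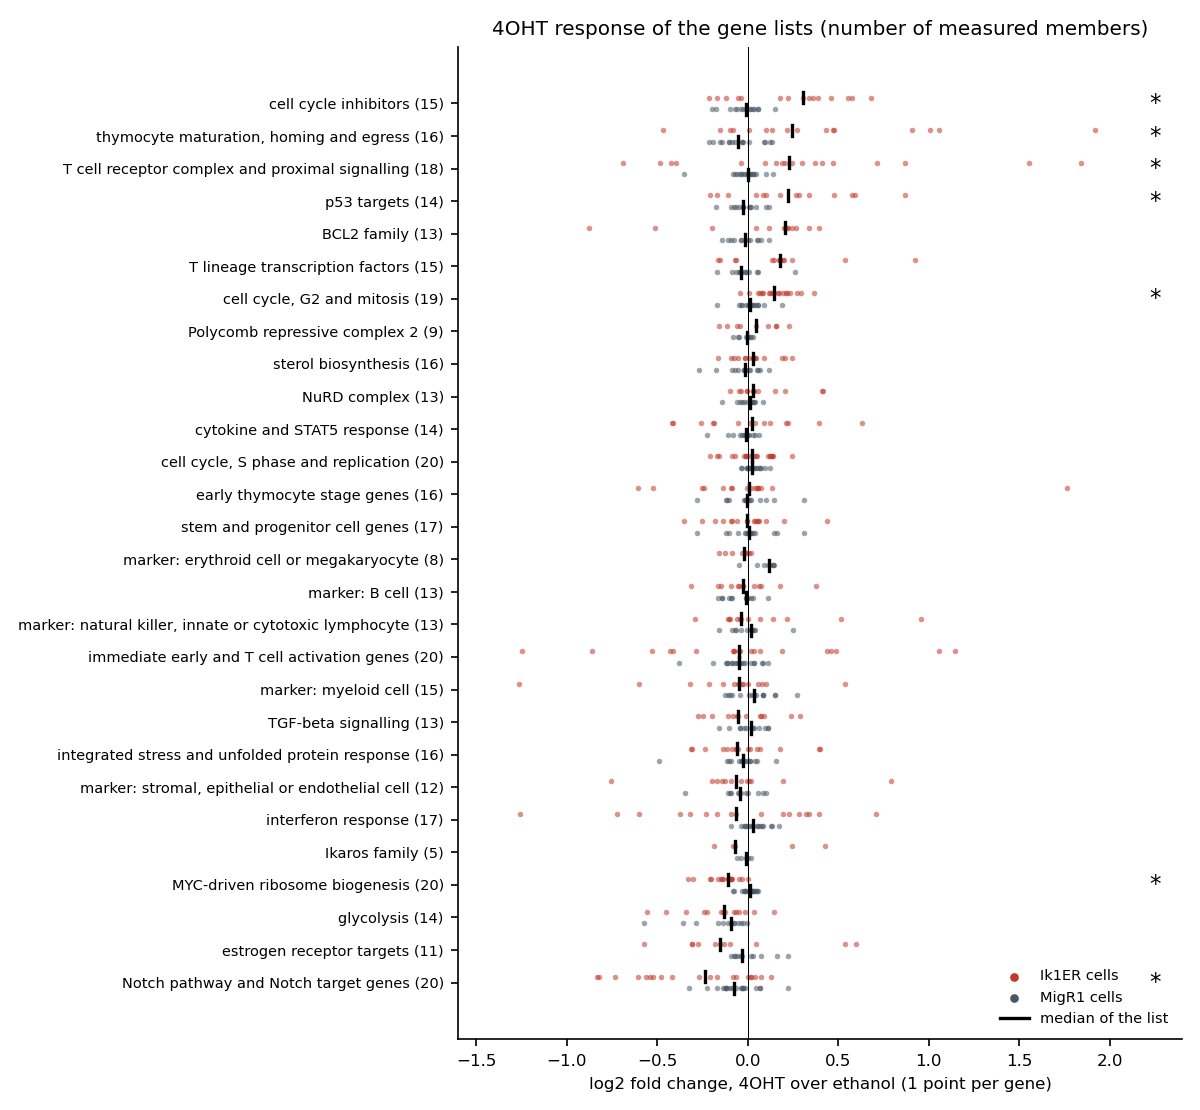
Log2 fold change with 4OHT over ethanol of every measured member (points) of the 28 gene lists, in Ik1ER and MigR1 cells, with the median of each list as a bar and the number of members in parentheses. A star marks the 7 lists called by camera with the preset correlation in Ik1ER cells, of which none was called with an estimated correlation.

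The other 21 lists were not called in Ik1ER cells (camera, adjusted p from 0.0658 to 0.897), and several held called genes of both directions. Among 17 interferon response genes the viral RNA sensor gene Ddx58 rose by 0.71 (SE 0.07, adjusted p = 0.00148) and Rsad2 by 0.39 (SE 0.08, adjusted p = 0.0276). The antiviral GTPase gene Mx1 changed by -1.26 (SE 0.15, adjusted p = 0.00392) and the sensor gene Ifih1 by -0.72 (SE 0.12, adjusted p = 0.0150), with 3 higher and 4 lower adjusted over the list alone. Of 20 immediate early and T cell activation genes, Dusp5 (0.49) and Nfkbia (0.46) rose while Ier3 (-1.25), Jun (-0.86), Tnfaip3 (-0.53) and Ier2 (-0.43) fell, or 5 and 5 adjusted over the list alone. Jun and Nfkbia were named after their values were seen. Other probe sets of Tnfaip3 (mean 7.08) and Jun (mean 5.56) read -0.16 and -0.29 and were not called. In the cytokine and STAT5 list of 14, the feedback inhibitor genes Socs1 and Socs3 went opposite ways, by 0.63 (SE 0.07, adjusted p = 0.00295) and -0.42 (SE 0.07, adjusted p = 0.0178), or 2 and 2 adjusted over the list alone. Greb1 rose by 0.60 among 11 estrogen receptor targets (2 higher and 1 lower adjusted over the list alone) and Trib3 by 0.40 among 16 genes of the integrated stress response (1 higher). The survival gene Bcl2l2 fell by 0.88 among 13 of the BCL2 family (1 lower adjusted over the list alone) and Aldoc by 0.56 among 14 of glycolysis (1 lower). Ddx58, Mx1, Ier3, Socs1 and Bcl2l2 kept their calls with each array left out. Without Ik1ER ethanol replicate 1 those of Nfkbia, Jun, Ier2, Socs3, Greb1, Rsad2, Trib3 and Aldoc were lost, and without Ik1ER ethanol replicate 2 those of Ifih1, Dusp5, Tnfaip3, Jun, Socs3, Rsad2, Trib3 and Aldoc. Without Ik1ER 4OHT replicate 1 Ifih1, Tnfaip3, Ier2, Nfkbia, Rsad2, Trib3 and Aldoc were not called, and without Ik1ER 4OHT replicate 2 Dusp5, Nfkbia, Socs3, Greb1 and Aldoc. Rsad2 and Trib3 were also lost without any MigR1 array, and Aldoc without either MigR1 4OHT array. The highest adjusted p was 0.154 for Rsad2, 0.205 for Trib3, 0.163 for Aldoc, 0.135 for Jun, 0.113 for Greb1, 0.105 for Socs3, 0.0998 for Nfkbia, 0.0993 for Dusp5, 0.0983 for Ier2, 0.0918 for Tnfaip3 and 0.0902 for Ifih1. The glycolysis list was called lower without Ik1ER ethanol replicate 1 (adjusted p = 0.00666), Ik1ER 4OHT replicate 2 (0.0162) or either MigR1 ethanol array (0.0408), and with the 3' to 5' covariate (0.0106).

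No gene was called among 15 T lineage transcription factors, 13 of the NuRD complex, with which Ikaros associates, and 9 of Polycomb repressive complex 2. The same held for 17 stem and progenitor genes, 16 of sterol biosynthesis and 13 of TGF-beta signalling, over all genes or adjusted over the list alone. Gata3 (0.54, adjusted p = 0.0766) and Runx3 (0.92, adjusted p = 0.115) were the nearest of the T lineage factors. The Ikaros family list of 5 held only Ikzf3 as a call, and 1 adjusted over the list alone. Markers of other cell types moved little as lists. Of 15 myeloid markers Cd14 changed by -1.26 (SE 0.10, adjusted p = 0.000556) and Lyz2 by -0.60 (SE 0.11, adjusted p = 0.0222) while Itgam, below the highest control in both groups, changed by 0.54 (SE 0.10, adjusted p = 0.0206), or 1 higher and 2 lower adjusted over the list alone. Of 13 markers of natural killer, innate or cytotoxic lymphocytes the granule protease gene Gzma rose by 0.96 (SE 0.12, adjusted p = 0.00475), from 12.74 ± 0.09 to 13.69 ± 0.09 (SD, n = 2), and the perforin gene Prf1 by 0.52 (SE 0.10, adjusted p = 0.0222), or 2 higher and 1 lower adjusted over the list alone. Pecam1, found on endothelium and leukocytes, rose by 0.79 (SE 0.09, adjusted p = 0.00294) among 12 stromal, epithelial or endothelial markers, or 1 higher adjusted over the list alone. None of 13 B cell and 8 erythroid or megakaryocyte markers was called either way. Cd14, Gzma and Pecam1 kept their calls with each array left out. Lyz2, Itgam and Prf1 lost theirs without Ik1ER ethanol replicate 1 or 2 or Ik1ER 4OHT replicate 1, and Prf1 also without Ik1ER 4OHT replicate 2 (adjusted p at most 0.131, 0.122 and 0.125). The myeloid list was called lower without Ik1ER 4OHT replicate 1 (adjusted p = 0.0495). The interferon list had a median of -0.07 but a positive camera direction, and the cytotoxic list a median of -0.04 and a mean of 0.09. The Ikaros family had a median of -0.07 and a mean of 0.07, and the early thymocyte list a median of 0.01 with a negative camera direction.

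The effect of 4OHT without Ik1ER was measured in MigR1 cells. Adm, which encodes the vasodilator peptide adrenomedullin, was the single gene called by limma, lower with 4OHT at a log2 change of -1.44 (SE 0.12, adjusted p = 0.0379). It read 5.95 in ethanol and 4.51 in 4OHT, and 4.84 and 4.43 in Ik1ER cells (n = 2 each). On the probe set used all but the first lie below the highest Bacillus control mean of 5.27, so that the size of the change is open. At an unadjusted p under 0.05 there were 386 genes. The glycolysis list was lower, with 14 of 14 members below 0, none of them called over all genes or adjusted over the list alone, and a median of -0.09 (camera, adjusted p = 0.000669, adjusted p = 0.931 with an estimated correlation). The 516 genes that rose in Ik1ER cells had a median change of 0.03 in MigR1 cells, against 0.59 in Ik1ER cells, and the 457 that fell had one of 0.02, against -0.61. The filter on dim genes left Adm untested. Its call was lost without any array except MigR1 ethanol replicate 2 and in 8 of the other alternatives, counting that filter. That of glycolysis was lost without MigR1 ethanol replicate 1 (adjusted p = 0.760) or MigR1 4OHT replicate 2 (0.244), over a range from 1e-07 to 0.760 in 12 settings. Without MigR1 ethanol replicate 2 the count of lists was 3, with immediate early genes and B cell markers lower too (adjusted p = 0.0470 each), and without MigR1 4OHT replicate 1 it was 2, with immediate early genes lower (0.0321). Without Ik1ER 4OHT replicate 1 or 2 it was also 2, with Notch lower (0.0221). The Notch list, which all arrays left uncalled in MigR1 cells (median -0.08, adjusted p = 0.118), was also called lower there with dim genes left out (0.00122) and without both replicate 2 arrays of Ik1ER (0.0165). Sterol biosynthesis took the place of glycolysis without MigR1 ethanol replicate 1 (0.00663) or MigR1 4OHT replicate 2 (0.00951).

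The difference between the 4OHT effects in Ik1ER and MigR1 cells was tested itself. Its largest positive values were those of Ms4a4b (2.97, SE 0.20, adjusted p = 0.00138), Ms4a4d (2.71, SE 0.25, adjusted p = 0.00393), Cxcr6 (2.27, SE 0.28, adjusted p = 0.0111), Tktl1 (2.06, SE 0.26, adjusted p = 0.0111) and Myl4 (2.05, SE 0.24, adjusted p = 0.00958). Negative values were largest for Rnf182 (-3.04, SE 0.26, adjusted p = 0.00322), Lmcd1 (-3.03, SE 0.20, adjusted p = 0.00138), Mpzl2 (-2.84, SE 0.23, adjusted p = 0.00250), Scn4b (-2.71, SE 0.18, adjusted p = 0.00138) and Ifi204 (-2.66, SE 0.37, adjusted p = 0.0175). limma called 229 genes, 113 positive and 116 negative. Of the 516 genes that rose in Ik1ER cells 112 had a positive call in this test, and of the 457 that fell 115 had a negative one. Among the genes named above, Fjx1 (-0.81, adjusted p = 0.0150), Cd3g (-0.70, adjusted p = 0.0490), Cd2 (1.22, adjusted p = 0.0382), Itgae (1.22, adjusted p = 0.0448) and Trp53inp1 (0.83, adjusted p = 0.0328) passed. Hes1 (-0.71, adjusted p = 0.287), Cd8a (1.74, adjusted p = 0.143) and Gzma (0.94, adjusted p = 0.0521) did not. Neither did Mcoln3 and Ifi202b, which were among the largest changes in Ik1ER cells. The sizes and ranks of Ms4a4d, Cxcr6, Rnf182 and Ifi204 are open here too, as each read below the highest control in an Ik1ER group. Of the 88 named genes called in Ik1ER cells 36 passed and 52 did not. By list, the test called 1 of the 5 Notch genes called in Ik1ER cells, 2 of 9 of the T cell receptor, 1 of 4 of maturation and homing, 1 of 4 p53 targets, 0 of 4 cell cycle inhibitors and 0 of 1 of MYC-driven ribosome biogenesis. The same 7 lists were called as in Ik1ER cells, in the same directions, but none with an estimated correlation. There Notch had an adjusted p = 0.396 with an estimated correlation, the T cell receptor list 0.346, maturation and homing, cell cycle inhibitors and p53 targets 0.198 each, G2 and mitosis 0.575 and MYC-driven ribosome biogenesis 0.545. The gene count fell to 66, 78, 71 and 51 without MigR1 ethanol replicate 1, MigR1 4OHT replicate 1, MigR1 ethanol replicate 2 and MigR1 4OHT replicate 2. It was 103 and 109 without Ik1ER ethanol replicates 1 and 2. The count was 439 with a trend and robust moderation, 100 without both replicate 2 arrays of Ik1ER and 575 with the 3' to 5' covariate. Single arrays ended the calls of Cxcr6 (adjusted p = 0.0511 without MigR1 ethanol replicate 1), Tktl1 (at most 0.0554 without that array or MigR1 4OHT replicate 2) and Myl4 (at most 0.0598 without MigR1 ethanol or 4OHT replicate 2). Ifi204 was lost without MigR1 4OHT replicate 1, MigR1 ethanol replicate 2 or either replicate 1 array of Ik1ER (at most 0.0647). Also ended by single arrays were the calls of the Notch list (0.0943 without Ik1ER 4OHT replicate 1) and of the ribosome list (0.0941 without Ik1ER ethanol replicate 1). Leaving out dim genes ended those of the receptor and homing lists (0.151 and 0.262). Sterol biosynthesis was called higher without MigR1 ethanol replicate 1 or MigR1 4OHT replicate 2 (0.0277 and 0.0297). Without Ik1ER 4OHT replicate 1 T lineage transcription factors were called higher and myeloid and erythroid markers lower (0.0430 each).

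Without inducer, Ik1ER and MigR1 cells were compared in ethanol. Adm (-1.10, SE 0.12) and the proto-oncogene Mycn (-0.92, SE 0.11), which read 13.80 in MigR1 and 12.88 in Ik1ER cells (n = 2 each), had the smallest p-values, both with an adjusted p of 0.267. They were followed by A530088E08Rik (-0.59), Olfr288 (-0.48) and Slc25a27 (-0.59). This ranking holds only the Ikzf1 probe set without a line difference. The other, tested among all probe sets, differed by 2.75 in ethanol (limma, unadjusted p = 1.0e-05, adjusted p = 0.274). Adm in Ik1ER cells (4.84) and Olfr288 in both lines (5.03 and 4.55) read below the highest Bacillus control mean of 5.27, so that the sizes of these differences are not known. limma called 0 of 18193 genes, with 955 at an unadjusted p under 0.05, and 0 of 28 lists. The count was 1 with the mean over the probe sets of a gene, which called Ikzf1 (1.39, adjusted p = 0.0122), 1 with the 3' to 5' covariate, which called Mycn (-0.93, adjusted p = 0.0372), and 0 in the other gene-level alternatives. 1 list was called without MigR1 ethanol replicate 2 (glycolysis, lower, adjusted p = 0.0394), without Ik1ER ethanol replicate 2 (integrated stress and unfolded protein response, lower, adjusted p = 0.00703) and without both replicate 2 arrays of Ik1ER (the same list, adjusted p = 0.00272).

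With inducer, Ik1ER cells were compared with MigR1 cells in 4OHT. Ms4a4b (3.22, SE 0.14, 9.29-fold, adjusted p = 0.000149), Ms4a4d (2.57, SE 0.17, adjusted p = 0.000414), the lymphoid coactivator gene Pou2af1 (2.37, SE 0.16, adjusted p = 0.000414), Myl4 (2.05, SE 0.17, adjusted p = 0.000801) and Gimap7 (1.95, SE 0.16, adjusted p = 0.000769) were higher in Ik1ER cells. Mpzl2 (-2.91, SE 0.16, adjusted p = 0.000149), Lmcd1 (-2.61, SE 0.14, adjusted p = 0.000149), Scn4b (-2.39, SE 0.13, adjusted p = 0.000149), Ifi202b (-2.34, SE 0.33, adjusted p = 0.00758) and Ifi204 (-2.18, SE 0.26, adjusted p = 0.00384) were lower. Mycn was lower here (-0.78, SE 0.11, adjusted p = 0.00737). In ethanol it had not been called, at -0.92 (SE 0.11, limma, unadjusted p = 2.9e-05, adjusted p = 0.267). Its measured difference between the lines was thus no smaller without inducer. The sizes of the differences of Ms4a4d and Gimap7, at 3.42 and 4.34 in MigR1 cells, and of Ifi204, at 3.40 in Ik1ER cells, are open. These means lie below the highest Bacillus control (5.27). limma called 928 genes, 532 higher and 396 lower, of which 399 higher and 317 lower were also called, in the same direction, for 4OHT in Ik1ER cells. Lists of these lengths would share 15.1 and 9.95 genes if independent, and 50 simulations of unchanged arrays with the same shared arrays gave 0. As these hold no effects to call, their 0 does not measure what the shared arrays add to the overlap. Across genes, which are not independent replicates, the fold changes of the 2 comparisons had a correlation of 0.876, against 0.50 simulated with no effect, and a covariance of 0.0520 against 0.00767. Both comparisons use the Ik1ER 4OHT arrays, from which part of the overlap may come. The same 7 lists were called, with an adjusted p of 0.162 with an estimated correlation for cell cycle inhibitors, 0.214 for Notch and for p53 targets, 0.297 for the T cell receptor, maturation and ribosome lists and 0.451 for G2 and mitosis. With the replicate number as a block T lineage transcription factors were called higher as well (adjusted p = 0.0353). The gene count was 293 without MigR1 4OHT replicate 1, 242 without MigR1 4OHT replicate 2, 429 with the arrays of the 2 groups alone and 594 without both replicate 2 arrays of Ik1ER. Without MigR1 4OHT replicate 1 the calls of Ifi202b (adjusted p = 0.0618) and of the maturation list (0.0836) were lost, and myeloid markers were called lower (0.0145). Without MigR1 4OHT replicate 2 that of the receptor list was lost (0.0673), and sterol biosynthesis was called higher (0.0105). Without Ik1ER 4OHT replicate 1 T lineage transcription factors were called higher (0.0413) and myeloid and erythroid markers lower (0.0167 and 0.0480). With dim genes left out the calls of the maturation and receptor lists were lost (0.650 and 0.301).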

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

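The tests of explanations for the called genes, for the hypoxia list and for the Ikzf1 probe sets were chosen after the result was seen, and only for the covariate test of the 3' to 5' signal was a prediction written before it was run. The test of the difference between the lines and its gene lists were chosen in advance.

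The 4OHT effect differed between Ik1ER and MigR1 cells for 229 genes by the test of the difference itself. The camera test of that difference called 7 lists, none of them with an estimated correlation. Among the genes that rose in Ik1ER cells the difference passed the threshold for Ms4a4b (2.97), Ms4a4d (2.71), Cxcr6 (2.27), Tktl1 (2.06), Myl4 (2.05), Gimap7 (2.01), Maf (1.95), Serpini1 (1.83), Igfbp7 (1.77), Ms4a6b (1.73), Kcna2 (1.61), Gimap6 (1.45), Ms4a6d (1.43), Cd2 (1.22), Itgae (1.22), Gbp8 (1.06), Trp53inp1 (0.83), Pecam1 (0.79), Gbp3 (0.79), Ddx58 (0.73) and Socs1 (0.59), on the log2 scale. Among those that fell it passed for Rnf182 (-3.04), Lmcd1 (-3.03), Mpzl2 (-2.84), Scn4b (-2.71), Ifi204 (-2.66), Cryab (-2.28), Lhfp (-2.27), Hfe (-2.19), Ifitm2 (-2.14), Gpr83 (-2.12), Uaca (-2.04), Cd14 (-1.30), Mx1 (-1.29), Fjx1 (-0.81) and Cd3g (-0.70). The sizes are open for those among them that read below the highest Bacillus control mean (5.27) in an Ik1ER group. The change of Igfbp7 is open as above, since its second probe set was not called for 4OHT in Ik1ER cells, and that of Myl4 likewise differed between probe sets.

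A response to 4OHT itself would move the 973 genes called in Ik1ER cells in MigR1 cells too, but their median change there, signed by their direction in Ik1ER cells, was 0.00549, against a median size of 0.597 in Ik1ER cells. Lower RNA or target quality of the replicate 2 arrays of Ik1ER would leave a pattern absent from the other pair of arrays, but of the 500 genes that differed most between the replicate 2 arrays 98.8% had the same sign between the replicate 1 arrays. As the whole cause a trend with the 3' to 5' signal of the transferrin receptor is argued against too. That signal differed by -0.0064 between the replicate 1 arrays and 0.25 between the replicate 2 arrays. Yet the changes of these 500 genes in the former followed those in the latter with a slope of 0.959. From ethanol to 4OHT the pyruvate carboxylase and Gapdh controls also fell between the replicate 1 arrays and rose between the replicate 2 arrays. The actin control fell in both pairs, from 0.353 to 0.297 and from 0.486 to 0.458, so that a trend with it is not argued against here. As part of the cause a trend with the 3' to 5' signal stays open. The ratio of 1.01 between fold changes with and without the covariate was nearly fixed by group means only 0.12 apart. Induced Ikaros activity stays a hypothesis, as does a response to 4OHT through the receptor part of the fusion protein, for which no control was analysed here.

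In the other direction, Adm was high in the MigR1 ethanol arrays alone. Hypoxia-responsive genes, a list of 23 written after Adm was seen, were highest on MigR1 ethanol replicate 1 (median deviation from the gene means 0.30) and next on Ik1ER ethanol replicate 2 (0.17). With 4OHT 22 of 23 were below 0 in MigR1 cells (median -0.20), and without Adm, which prompted the list, 21 of 22 (median -0.19, p = 0.0917 with an estimated correlation, which allows for genes that move together). A response to 4OHT in both lines stays open, since 19 of 23 were below 0 in Ik1ER cells (median -0.12, and without Adm 18 of 22, p = 0.479 with an estimated correlation) and the difference of the effects had a median of 0.08 (without Adm 0.05, p = 0.789). A state of the MigR1 ethanol cultures also stays open, since 16 of the 23 were lower in Ik1ER than in MigR1 cells in ethanol (median -0.19, and without Adm 15 of 22, p = 0.297 with an estimated correlation).

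Of the 2 Ikzf1 probe sets, the one dimmer in MigR1 cells was 2.64 higher on the log2 scale in the 4 Ik1ER than in the 4 MigR1 arrays, and the other was not. Whether a transcript of the introduced gene raised it cannot be told apart from another difference between the lines, since this value itself raised the question and each line is 1 transduced population. Which parts of the transcript the probe sets read was not analysed here.

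Outside the named genes, 84 of the 9160 probe sets without a listed symbol were called for 4OHT in Ik1ER cells, 49 higher and 35 lower, against 0 in MigR1 cells by limma.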

How the results depend on the processing

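The alternatives without both replicate 2 arrays of Ik1ER and with the 3' to 5' covariate were chosen after the results were seen; the others were planned. For 4OHT in Ik1ER cells, all 973 called genes kept their sign without both replicate 2 arrays and with each Ik1ER array left out. They also kept it with the replicate block, with the covariate and with each MigR1 array left out. The block and the loss of a MigR1 array cannot change these fold changes, so that the signs there were fixed in advance. With the covariate they were nearly fixed, as the group means of the control differed by only 0.12. Calls were kept by 942 of the genes with the block and 971 with the covariate. The count of 973 moved to 412 with the arrays of the 2 groups alone and 153 with an absolute log2 fold change of at least 1. It was 388 without both replicate 2 arrays and 1560 with the covariate, and ranged from 439 to 827 with 1 array left out. It was 913 to 1342 in the other settings. The arrays share replicate numbers between groups, but no label says that a number marks a batch. Deviations of same-numbered arrays correlated by 0.27 between the MigR1 groups, 0.45 between the Ik1ER groups, 0.10 between the ethanol groups and -0.07 between the 4OHT groups. With the number as a block the counts were 1151 for Ik1ER, 0 for MigR1 and 335 for the difference. For the lines they were 0 in ethanol and 1082 in 4OHT. The filter on dim genes removed Adm, the single gene called in MigR1 cells, so that its call could not be kept there. For 4OHT in MigR1 cells the count of 1 became 0 with the block, the filter on dim genes, repeated quantile normalization, the mean over probe sets, every probe set, the 2 groups alone, both replicate 2 arrays left out and the covariate, and was 0 to 1 with 1 array left out. The difference moved from 229 to 439 with trend and robust settings, 112 with the fold change threshold, 100 without both replicate 2 arrays and 575 with the covariate, and ranged from 51 to 269 with 1 array left out. In ethanol the count of 0 became 1 with the mean over probe sets and 1 with the covariate. In 4OHT the count of 928 moved to 429 with the 2 groups alone, 141 with the fold change threshold and 594 without both replicate 2 arrays, and ranged from 242 to 812 with 1 array left out. Called lists went from 7 to 0 for Ik1ER, for the difference and for the lines in 4OHT, and from 1 to 0 for MigR1, with an estimated correlation. The 1 list called in MigR1 cells became 3 with dim genes left out and 2 without both replicate 2 arrays of Ik1ER, both times with Notch lower among them (adjusted p = 0.00122 and 0.0165), and 1 to 3 with 1 array left out, and the 0 lists in ethanol became 1 without both replicate 2 arrays and 0 to 1 with 1 array left out. Of 109 calls on named genes, 46 were lost without both replicate 2 arrays and 37 with the 2 groups alone, against 0 to 13 in the other settings that kept all 8 arrays. With 1 array left out 11 to 36 were lost, and fewer arrays leave fewer degrees of freedom, whereas for changes between fits of all 8 arrays the cause was not tested. The filter on dim genes removed those below its cut untested, so that its 0 losses cover only the genes it kept. Signs turned only among named genes that were not called. Without both replicate 2 arrays Blnk was at -0.072 and Epor at 0.0074. With 1 array left out the range was -0.027 to 0.38 for Blnk, -0.38 to 0.063 for Epor, -0.20 to 0.044 for Ikzf5 and -0.029 to 0.33 for Chd4. It was -0.21 to 0.013 for Mta1, -0.084 to 0.016 for Itga2b and -0.25 to 0.12 for Ikzf4. Signal over background limits dim genes, whose changes RMA compresses: the probe set median was 5.40 and the highest Bacillus control mean 5.27. Of 88 named genes called for 4OHT in Ik1ER cells, 22 read below 5.27 in at least 1 of the groups, so that the sizes of their changes are open. These were Ms4a4c, Ms4a4d, Ms4a6d, Gimap7, Gimap8, Itgam, Kcna2, Cd44, Cxcr6, Itgae, Gbp2, Gbp8, Cd2 and Klf2 in ethanol, and Ifi204, Ifitm3, Mx1, Rnf182, Lyz2, Cryab, Lhfp and Jun in 4OHT. Of these 22, 3 (Ms4a4c, Itgam and Ifitm3) read below it in both groups and have no level above the controls. The changes of the other 19 may be compressed. For Jun, among the 19, another probe set above the highest control (mean 5.56) read -0.29 (limma, adjusted p = 0.282).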

Other observations

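The families and genes in this part were chosen after the data were seen, and so were their tests. Among 448 families of genes with a shared symbol stem and at least 6 measured members, limma's calls for 4OHT in Ik1ER cells were enriched in the Gbp genes, which encode interferon-inducible guanylate-binding proteins. Of 6 measured, 5 rose and none fell (Fisher's exact test, adjusted p = 4.73e-05). Gbp2 rose by 1.36 (SE 0.21, adjusted p = 0.0102), Gbp8 by 1.04 (SE 0.08, adjusted p = 0.000526), Gbp3 by 0.83 (SE 0.08, adjusted p = 0.00178), Gbp7 by 0.66 (SE 0.11, adjusted p = 0.0119) and Gbp6 by 0.45 (SE 0.09, adjusted p = 0.0327). Over the same comparison Ifitm2 and Ifitm3, also interferon-inducible, changed by -2.04 and -0.71 (adjusted p = 0.000692 and 0.00727), the latter below the highest Bacillus control in both groups. The other 5 of the 7 Ifitm genes were not called, and the family did not pass for falls (Fisher's exact test, adjusted p = 0.908). Gbp3 and Gbp8 kept their calls with each array left out, whereas Gbp2, Gbp6 and Gbp7 lost theirs without Ik1ER ethanol replicate 1. Gbp2 and Gbp6 were also lost without Ik1ER 4OHT replicate 1, and Gbp6 without Ik1ER ethanol replicate 2 or either MigR1 4OHT array (adjusted p at most 0.0676, 0.170 and 0.0788). The difference of the 4OHT effect from MigR1 cells was called for Gbp8 and Gbp3 (limma, adjusted p = 0.00627 and 0.0255). It was not called for Gbp2, Gbp7 and Gbp6 (limma, adjusted p = 0.0513, 0.156 and 0.156). Members of this family are alike in sequence, so that a probe set may read more than 1 of them, and calls in a family are then not independent of each other.

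The Ms4a family had 5 of 17 members higher and none lower (Fisher's exact test, adjusted p = 0.0125). Besides Ms4a4b, Ms4a4d and Ms4a6b, the members Ms4a6d (1.6, SE 0.14, adjusted p = 0.000977) and Ms4a4c (0.54, SE 0.08, adjusted p = 0.0102) rose. Ms4a4c read 3.16 in ethanol and 3.71 in 4OHT, both below the highest Bacillus control mean (5.27), so that its call rests on no level above the controls. The changes of Ms4a4d, Ms4a6d, Gbp2, Gbp8, Gimap7 and Gimap8, below the highest control in ethanol alone, may be compressed, and their sizes are open. Ms4a4c lost its call without Ik1ER ethanol replicate 2 (adjusted p = 0.0710). For Ms4a4b, Ms4a4d, Ms4a6b and Ms4a6d the difference of the 4OHT effect from MigR1 cells was called, but not for Ms4a4c (limma, adjusted p = 0.0796). The Pdlim genes, which encode cytoskeletal adaptors with PDZ and LIM domains, had 3 of 6 higher (Fisher's exact test, adjusted p = 0.0477). They were Pdlim4 (1.42, SE 0.20, adjusted p = 0.00653), Pdlim2 (1.03, SE 0.13, adjusted p = 0.00428) and Pdlim5 (0.57, SE 0.07, adjusted p = 0.00302). The difference of the 4OHT effect from MigR1 cells was called for none of the 3 (limma, adjusted p = 0.0743, 0.105 and 0.0600). Of the Gimap genes, lymphocyte GTPases of 1 gene cluster, 3 of 8 rose, which did not pass (Fisher's exact test, adjusted p = 0.102): Gimap7 (1.98), Gimap8 (1.58, SE 0.28, adjusted p = 0.0160) and Gimap6 (1.41, SE 0.12, adjusted p = 0.000784). Gimap8 lost its call without Ik1ER ethanol replicate 1 or 2 or Ik1ER 4OHT replicate 1 (adjusted p at most 0.101). For Gimap7 and Gimap6 the difference of the 4OHT effect from MigR1 cells was called, but not for Gimap8 (limma, adjusted p = 0.127). Genes whose symbol is Cd followed by a number, apart from such stems as Cdk and Cdc, had 12 of 89 higher and 6 lower (Fisher's exact test for higher, adjusted p = 0.00174). No family passed for falls.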
